A study of Mus musculus with 12 samples.

How the data were processed

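RNA from the ears of wild-type mice was sequenced in 12 libraries, 4 in each of 3 groups. Per the labels, the Blank group received no treatment, the Model group received MC903, a vitamin D analogue that induces a dermatitis resembling atopic dermatitis, and the IsoL group received isoliensinine, a plant alkaloid. The sources used here do not give the strain, the doses, the days of sampling, or whether the IsoL ears also received MC903. The series states that all groups hold biological replicates, but the labels do not tie each library to a separate animal, so the p-values measure the spread between these libraries. Per the labels, RNA was isolated with Trizol, mRNA was captured on poly-T beads, cDNA was made from random primers and the libraries were amplified in a 15-cycle PCR. No molecular identifiers are described, so the intervals and floors given for counts cover counting error only.

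The authors list fastp 0.22.0, HISAT2 2.1.0 and HTSeq 0.9.1 as their tools. The deposited table holds 56691 genes, each with a raw read count and an FPKM value per library, a gene symbol, an exonic length, coordinates and pathway annotation. The deposited FPKM values were recomputed from the deposited counts, the exonic length and the total count of each library, and 100% of the values in every library were equal within the rounding of the table. The genome build is not given in the sources used here. Of the identifiers, 52073 were found in GENCODE M21 (GRCm38), but only 1472 of these (2.83%) had the same start and end there, so all coordinates are those of the deposited table.

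The tests were run on the deposited counts. Total counts ran from 13884927 to 18771831 per library. Genes with an FPKM of 1 or more in at least 4 of the 12 libraries were tested, which left 15403. Counts were scaled with TMM factors, and each gene was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 fit for the 3 groups and no covariate. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called changed at an adjusted p under 0.05. Levels are TMM-scaled CPM values, given as mean ± SD over 4 libraries, and log2 fold changes are given ± SE. The plan made before the data were examined assumed that only FPKM would be available and named limma-trend on log2(FPKM + 1); because counts were deposited, the count test was used as the main one, and limma-trend, run with limma 3.58.1, became an alternative, both decided after the table was seen.

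Before the data were examined, 33 gene lists were fixed for the tissue and the treatment. They cover the vitamin D response, cathepsins, cystatins and stefins, the lysosome, IL-17 and IL-23 cytokines and receptors, the IL-17 response of keratinocytes, type 2 cytokines and receptors, type 2 chemokines and effector genes, the interferon response, keratinocyte activation, epidermal differentiation, barrier lipids, the cell cycle, mitochondrially encoded genes, and immediate early and handling genes. The others hold markers of neutrophils, eosinophils, basophils, mast cells, T cells, B and plasma cells, monocytes and macrophages, dendritic and Langerhans cells, sebaceous gland, fibroblasts and matrix, endothelium, skeletal muscle, cartilage, adipocytes, hair follicle keratins, nerve and Schwann cells, melanocytes and erythrocytes. Several lists share members, such as Il6, which the basophil list and the IL-17 and IL-23 list both hold. A list with at least 3 tested members was tested against all other genes with camera on the gene statistics, with a preset correlation of 0.01 between genes, and the p-values were adjusted over the lists of a comparison. Camera with an estimated correlation, which runs on the counts and not on the gene statistics, and fry, which tests whether the members move on balance one way and does not compare them with other genes, were alternatives.

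Named genes followed a rule fixed in advance. It takes, in each comparison, the 8 largest rises and the 8 largest falls among called genes whose libraries do not overlap between the groups, whose mean FPKM is 5 or more in the higher group and whose symbol is not a predicted-gene name. It adds a panel of 17 genes and up to 3 called members with the largest change from each list. Members named because few genes of a list went against its other members were chosen after their values were seen. Il17a and Il13, panel genes that did not pass the expression filter, were compared with an exact two-sided permutation test of their CPM values, adjusted over the tests of Il17a and Il13 in the 3 comparisons. Where a group had no counts, the fold was computed against a floor of 3 counts over the group and is given as a lower bound. Shared sequence was measured as the percent of 50-base words of a gene's GENCODE M21 transcripts that also occur in another gene.

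The test was checked on simulated data made from these libraries. In simulated counts for Model against Blank, 87.8% of genes with a 2-fold change and 96.0% with a 4-fold change were called, and 8 of 15179 unchanged genes were called. Only a small part of the genes was changed there, and each gene had the same spread in all groups. The simulation thus does not cover data in which most genes move, or a wider spread in a single group. Alternatives fixed in advance were another pseudocount, no filter and a stricter one, median-ratio, quantile and TPM scaling, a fit of only the 2 groups compared, the replicate number as a block, library weights, a robust fit, a fold threshold and leaving out each library. Those on pseudocount, quantile and TPM scaling and library weights need log values and were run with limma-trend, so they change the test as well. DESeq2 1.42.0, a fit without scaling factors and the KEGG pathways of the deposited annotation were added after seeing the data. Figures were drawn with matplotlib 3.10.9. No sample was left out.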

Results

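Expression was measured in 12 libraries from the ears of wild-type mice, 4 untreated (Blank), 4 given MC903 (Model) and 4 given isoliensinine (IsoL). The total counts of replicates 1 to 4 were 17004780, 16393357, 15791536 and 16078167 in Blank, 13884927, 17213227, 15173338 and 15340003 in Model, and 18771831, 17635501, 16493348 and 18679867 in IsoL. The tested genes held 99.2% to 99.4% of the counts of every library, and mitochondrially encoded genes held 8.11% to 9.37%. The most abundant gene in each library was mt-Co1, with 2.64% to 3.52% of the counts.

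The libraries separated by group. The first principal component held 74.7% of the variance and placed Blank at -91.6 to -88.2, IsoL at 25.6 to 32.5 and Model at 60.0 to 64.7. The second held 14.8% and placed IsoL at -43.6 to -32.4, Blank at 7.07 to 9.19 and Model at 26.6 to 33.4. The spread between libraries of a group, as the common biological coefficient of variation, was 3.57% in Blank, 4.70% in Model and 9.20% in IsoL.

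**Figure D1:**
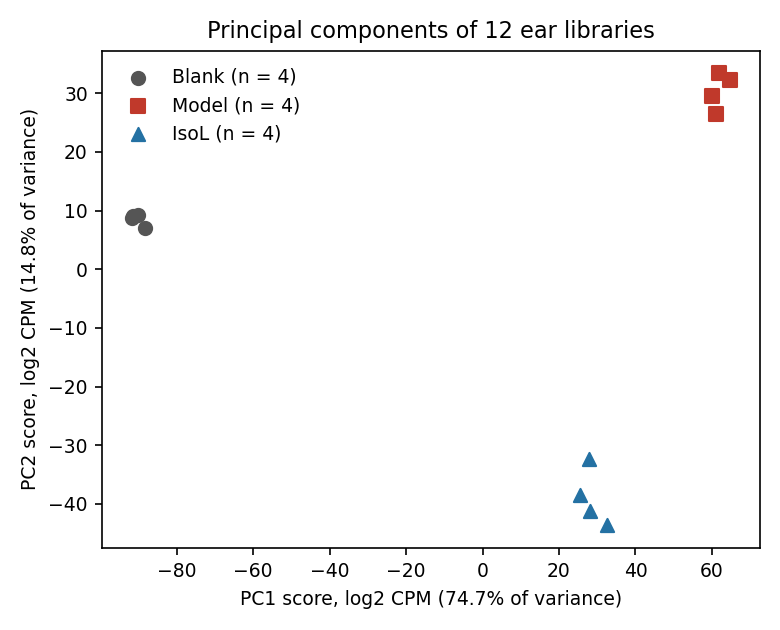
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, 1 point per library, with the percent of variance on each axis. The 4 IsoL libraries lie between Blank and Model on the first component and below both on the second.

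Model against Blank asks how MC903 ears differ from untreated ones. Blank received no treatment, so effects of the application itself cannot be told apart from those of MC903. The MC903 ears carried far higher levels of neutrophil genes and of the keratinocyte genes that IL-17 induces, and eosinophil, basophil, mast cell, and monocyte and macrophage genes were higher as well. Cxcl2, a chemokine that draws neutrophils, had 1.80 ± 0.869 CPM in Blank and 1209.7 ± 71.0 CPM in Model (n = 4 each), a 664-fold rise. Ctsb, the lysosomal protease cathepsin B (ENSMUSG00000021939, chromosome 14, 63359911 to 63383372, build not given), rose 4.79-fold, from 384 ± 4.87 to 1840.05 ± 58.9 CPM, with an adjusted p of 1.0e-20. Cyp24a1, the enzyme that degrades active vitamin D and a direct target of its receptor, rose by 10.27 ± 0.11 on the log2 scale.

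Of 21 tested neutrophil markers, 20 rose and 1, Mpo, fell (adjusted p = 1.4e-12). Their median log2 change was 7.98, or 6.93 with the 2 members without counts in Blank at their bound. Ly6g, a surface marker of neutrophils, had no counts in Blank and 294 in Model, which is at least 114-fold higher, and Ngp, a granule protein, was at least 122-fold higher. S100a8 and S100a9, the subunits of calprotectin, rose by 5.85 ± 0.17 and 6.07 ± 0.20, and Csf3r, the receptor of granulocyte colony-stimulating factor, rose by 7.58 ± 0.12. Mpo, myeloperoxidase, fell by 2.05 ± 0.19, from 6.77 ± 1.23 to 1.63 ± 0.350 CPM. In the IL-17 response list 21 of 22 genes rose and none fell, with a median of 5.22 (adjusted p = 1.5e-11). Its largest rises were in the chemokines Cxcl5 (9.91 ± 0.13), Cxcl3 (9.68 ± 0.13) and Cxcl2, and Cxcl1 rose by 5.81 ± 0.10. Among 11 IL-17 and IL-23 cytokines and receptors, 5 rose and 6 fell, and the list was not called (adjusted p = 0.523); its median was -0.29 and its mean 1.64. Without the filter on low values it was called higher (0.022, with 0.022 to 0.633 over 21 settings). Il1b (8.31 ± 0.15), Il6 (7.01 ± 0.20), Il23a (4.88 ± 0.40), Il1r1 and the receptor Il17ra (1.53 ± 0.05) rose. Il17a itself (ENSMUSG00000025929) lay below the filter, with 0 counts in Blank and 17 in Model, at least 6.6-fold higher. An exact permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow, and 0.0429 after adjustment.

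Of 12 type 2 cytokines and receptors, 11 rose and Gata3 fell (median 1.45, adjusted p = 0.000111). Tslp, the epithelial cytokine that drives type 2 inflammation (ENSMUSG00000024379, chromosome 18, 32948436 to 32952850), rose 36.4-fold, from 5.27 ± 1.44 to 192 ± 27.8 CPM, and Il4 rose by 1.41 ± 0.21. Il13, also below the filter, had 13 counts in Blank and 62 in Model, a ratio of 5.56 (95% counting interval 3.02 to 11.02, exact permutation p = 0.0286, adjusted 0.0429). Of 14 type 2 chemokines and effector genes, 9 rose and 4, Ccl22, Ccr4, Retnla and Postn, fell (median 4.02, adjusted p = 0.00605), with Chil3 up by 9.37 ± 0.13. All 5 eosinophil markers (median 5.09, adjusted p = 0.00197), all 7 basophil markers (3.11, 0.000313) and all 16 monocyte and macrophage markers (2.83, 1.4e-12) rose. Ccr3, the eotaxin receptor, rose by 5.63 ± 0.18, Mcpt8 by 7.67 ± 0.33 and Cd14 by 6.75 ± 0.10. Among 9 mast cell markers 8 rose and Mrgprb2 fell (median 1.29, adjusted p = 0.000891), and among 20 interferon response genes 18 rose and Mx2 fell (1.15, 5.3e-08), with Cxcl9 up by 6.05 ± 0.13. Of 14 T cell markers, 11 rose and Cd3g and Trdc fell (median 1.75, adjusted p = 0.0021). That call was lost at adjusted p = 0.149 with an estimated correlation. Of 10 dendritic and Langerhans cell markers, 8 rose and Cd207 and Mgl2 fell (median 0.85, adjusted p = 0.0268; adjusted p = 0.428 with an estimated correlation). The B and plasma cell list had too few tested members for a test; its tested genes Ighm and Igkc both rose.

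Cathepsins as a group rose: 11 of 14 were higher and Ctsf was lower (median 1.40, adjusted p = 2.0e-05), with Ctse up by 5.06 ± 0.23 and Ctss, the cathepsin of antigen-presenting cells, by 3.72 ± 0.06. Their inhibitors rose as well, with 11 of 12 cystatins and stefins higher and Cst3 lower (median 5.67, adjusted p = 3.2e-06). Among 24 lysosome genes 19 rose (median 0.76, adjusted p = 1.7e-06). Of 8 vitamin D response genes, 7 rose and Trpv6 fell (median 4.36, adjusted p = 0.00048). Immediate early and handling genes, which also respond to tissue handling, rose in 13 of 17 and fell in Fosb, Hspa1a and Hspa1b (median 1.72, adjusted p = 3.8e-05).

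In the epidermis, keratinocyte activation genes rose in 16 of 19, with Serpinb3b and Ereg lower (median 4.10, adjusted p = 1.5e-07). Krt16, a keratin of activated keratinocytes, rose 42.2-fold. Epidermal differentiation genes went both ways, 11 up and 13 down of 25, and the list was not called (adjusted p = 0.523, median -0.22, mean 0.07). The filaggrin gene Flg rose by 1.64 ± 0.12 and Rptn by 7.29 ± 0.11, whereas Flg2 fell by 3.01 ± 0.09. Barrier lipid genes were not called either (adjusted p = 0.188, median -0.34, mean 0.05), with 10 of 15 lower and Degs2 up by 3.60 ± 0.14. Hair follicle keratins rose in 14 of 15 and Msx2 fell (median 1.62, adjusted p = 0.0153; adjusted p = 0.811 with an estimated correlation). Sebaceous gland genes fell in 8 of 14 and rose in none (median -0.78, adjusted p = 0.00167; adjusted p = 0.187 with an estimated correlation). Cell cycle genes rose in 19 of 20 (median 0.56, adjusted p = 0.000276; adjusted p = 0.449 with an estimated correlation).

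Endothelial markers rose in 12 of 14 and fell in none (median 1.73, adjusted p = 8.4e-07), with the adhesion molecule Selp up by 4.06 ± 0.08. Fibroblast and matrix genes rose in 16 of 20, and Col6a1, Fap and Sparc fell (median 0.54, adjusted p = 0.000114; adjusted p = 0.0831 with an estimated correlation). All 16 skeletal muscle genes fell (median -0.87, adjusted p = 8.6e-06; adjusted p = 0.437 with an estimated correlation), and their share of counts was 0.618% to 0.672% in Blank, 0.313% to 0.360% in Model and 0.266% to 0.423% in IsoL. Cartilage genes fell in 12 of 13 (median -1.27, adjusted p = 2.5e-06; adjusted p = 0.2 with an estimated correlation). Nerve and Schwann cell genes fell in 8 of 11 and Scn7a rose (median -0.65, adjusted p = 0.0021; adjusted p = 0.0831 with an estimated correlation). The 4 erythrocyte genes Hba-a1, Hbb-bs, Hbb-bt and Alas2 rose (median 1.13, adjusted p = 0.0352; adjusted p = 0.437 with an estimated correlation). Adipocyte (adjusted p = 0.205, 2 up, Fabp4 and Lipe, and 6 down of 10), melanocyte (0.446, Dct and Mitf up of 5) and mitochondrially encoded genes (0.747) were not called. Of the latter, mt-Nd1 rose by 0.19, a direction that reversed to -0.04 with TPM scaling, and mt-Nd2 fell by 0.15.

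The rises named by the rule were, among genes with counts in Blank, in Cyp24a1, Saa3, Cxcl5, Cstdc4 and Ccl4, in falling order. The others, without counts in Blank and so without a place in that order, were the mast cell proteases Mcpt1 (at least 240-fold) and Mcpt2 (at least 193-fold) and Art2a (at least 164-fold). The largest falls were in Akr1c14 (-3.65 ± 0.10), Ndufs5-ps, Mrgprb9-ps, Krt24, Il1f10, Col4a6, Calm5 and Flg2. By edgeR, 10805 of 15403 genes changed, 5436 up and 5369 down, and 2149 rose and 1104 fell at least 2-fold. The 4 Model and 4 Blank libraries did not overlap for 10374 genes, where chance gives 2.86%. Of the 32 lists tested, 26 were called, 22 up and 4 down, and 16 of the calls held with an estimated correlation: all but the 10 whose p with it is given above. For these 16 the adjusted p with it ran from 0.00212 (vitamin D response among others) to 0.0430 (lysosome). Adjusted over the list alone, the counts were the same for 31 of the 32 lists, and in the mitochondrially encoded list 1 gene rose and 0 fell. The split between rises and falls depended on scaling: 50.3% of the called genes rose with TMM, 38.9% without scaling factors, 36.8% with quantile and 32.4% with TPM values, which moved the median change of all genes to -0.15, -0.14 and -0.22. The melanocyte gene Dct, up by 0.30, was not called without Model replicate 3 (0.22), nor was mt-Nd2 without Model replicate 2 (-0.12).

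**Figure D2:**
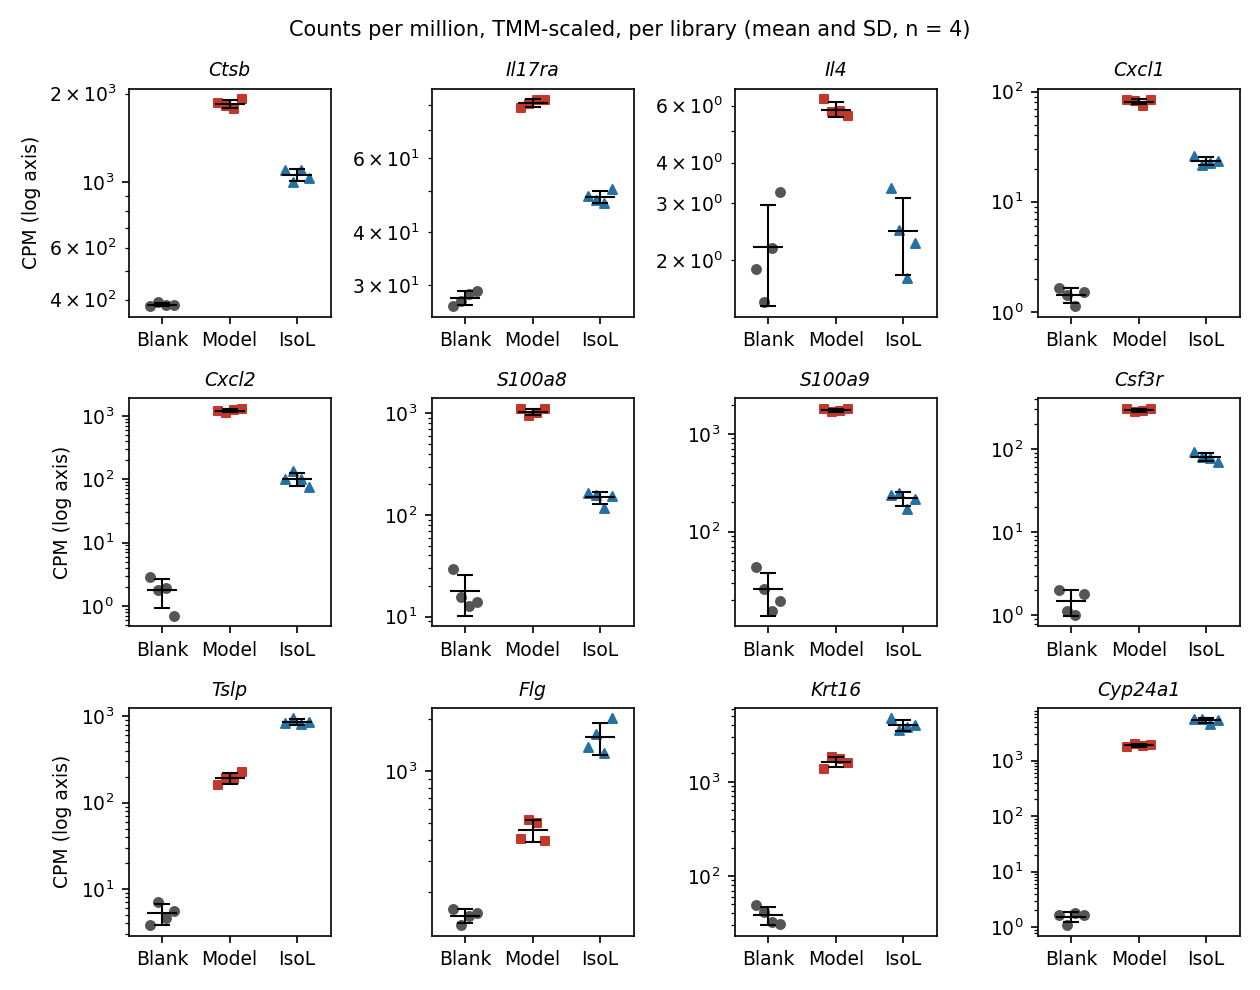
CPM of 12 panel genes (y axes, log scale) in each library of the 3 groups, with the mean and SD of 4 libraries. Ctsb, Cxcl1, Cxcl2, S100a8, S100a9 and Csf3r are highest in Model, while Tslp, Flg, Krt16 and Cyp24a1 are highest in IsoL.

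IsoL against Model asks how isoliensinine ears differ from MC903 ears. Neutrophil, eosinophil, monocyte and interferon response genes were lower in IsoL, and genes of epidermal differentiation were higher. Ctsb fell by 0.80 ± 0.05 on the log2 scale, from 1840.05 ± 58.9 to 1059 ± 48.5 CPM (n = 4 each, adjusted p = 2.3e-12), a 1.74-fold difference. Cxcl2 fell by 3.57 ± 0.13, to 102 ± 23.6 CPM. Tslp went the other way, from 192 ± 27.8 to 859 ± 59.3 CPM, a 4.48-fold rise.

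Among the 21 neutrophil markers 19 fell and Padi4 rose (median -2.82, adjusted p = 3.7e-17). Retnlg fell by 4.65 ± 0.13, Ly6g by 4.60 ± 0.31, S100a8 by 2.80 ± 0.14 and Csf3r by 1.86 ± 0.07, and S100a9 fell to 219 ± 34.7 CPM. Mpo did not pass the test (-0.40 ± 0.25, adjusted p = 0.191), and with quantile scaling its change was 0.01. Of 22 IL-17 response genes, 15 fell and 5 rose (median -0.93, adjusted p = 0.00023); adjusted over the list alone, 6 rose. The risers were the antimicrobial genes Defb4, Defb14 and Slpi and the cytokines Il36b and Il36g. Cxcl1 fell by 1.78 ± 0.07, Cxcl3 by 3.36 ± 0.07, Cxcl5 by 1.77 ± 0.06, and Csf3, the cytokine that mobilises granulocytes, fell from 14.4 ± 2.11 to 1.80 ± 0.775 CPM. Among the IL-17 and IL-23 cytokines and receptors, Il1b (-2.84 ± 0.10), Il23a (-2.81 ± 0.31), Il6 (-1.84 ± 0.11), Il17ra (-0.74 ± 0.05) and Il1r1 fell and Il17rc, Il17re and Traf3ip2 rose; the list was not called (adjusted p = 0.127, median 0.07, mean -0.65), but was called lower with DESeq2 (0.0447) and without the filter on low values (0.00265, with 0.00265 to 0.363 over 21 settings). Il17a had 2 counts in IsoL against 17 in Model, a ratio of 0.105 (95% counting interval 0.0118 to 0.443, exact permutation p = 0.0286, adjusted 0.0429).

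Type 2 cytokines and receptors fell in 9 of 12 and rose in Tslp (median -0.68, adjusted p = 0.00448), with Il4 down by 1.24 ± 0.21 and Il1rl1, the IL-33 receptor, by 1.95 ± 0.08. Il13 had 27 counts in IsoL against 62 in Model, a ratio of 0.389 (0.238 to 0.621, exact permutation p = 0.0286, adjusted 0.0429). Type 2 chemokines and effector genes fell in 9 of 14, with Ccl24, an eotaxin, down by 4.41 ± 0.10, and rose in Ccl22 and Retnla (median -1.69, adjusted p = 0.000195). All 5 eosinophil markers fell (median -3.20, adjusted p = 0.00021), as did all 16 monocyte and macrophage markers (-0.82, 3.2e-11). All 20 interferon response genes fell (median -1.75, adjusted p = 6.8e-22), among them Rsad2 by 3.60 ± 0.08, Oasl1 by 2.83 ± 0.09 and Ifit2 by 2.64 ± 0.08. Of 7 basophil markers, Mcpt8, Gata2, Il4, Il6 and Cd69 fell (median -0.98, adjusted p = 0.00565; adjusted p = 0.0792 with an estimated correlation). T cell markers fell in 10 of 14 (11 adjusted over the list alone, median -0.65, adjusted p = 0.001; adjusted p = 0.21 with an estimated correlation). Dendritic and Langerhans cell markers were not called (adjusted p = 0.532), with Itgax, H2-Eb1, Cd74 and Clec10a lower and Cd207 and Mgl2 higher. Mast cell markers were not called (adjusted p = 0.77, median 0.02, mean -0.17), with Hdc and Tpsab1 lower and Cma1, Mrgprb1 and Mrgprb2 higher.

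Cathepsins fell in 9 of 14 and Ctsd, Ctsh and Ctsl rose (median -0.46, adjusted p = 0.0032; adjusted p = 0.103 with an estimated correlation). Ctss fell by 1.53 ± 0.06 and Ctsk by 0.91 ± 0.06. Lysosome genes fell in 17 of 24 (median -0.36, adjusted p = 3.1e-06; adjusted p = 0.0973 with an estimated correlation). Cystatins and stefins were not called (adjusted p = 0.124), with Stfa2l1 down by 3.09 ± 0.07, Cstdc4 and Cst7 also down and 7 of 12 up; without the filter on low values the list was called higher (0.00728, with 0.00728 to 0.823 over 21 settings). The vitamin D response list was not called (adjusted p = 0.538, median 0.60): Cyp24a1 (1.49 ± 0.07), Vdr, Trpv6, S100g and Tslp rose and Cd14, Il1rl1 and Car2 fell. For both lists the test with an estimated correlation gave the other sign. Immediate early and handling genes fell in 14 of 17 and rose in Hspa1a and Hspa1b (median -0.91, adjusted p = 4.6e-08).

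All 25 epidermal differentiation genes rose (median 1.24, adjusted p = 2.4e-18), among them Tgm3, a transglutaminase of the cornified envelope, by 1.83 ± 0.11, Flg by 1.80 ± 0.11 and Cdsn by 1.75 ± 0.08. All 15 barrier lipid genes rose (median 0.87, adjusted p = 2.6e-09; adjusted p = 0.0973 with an estimated correlation), with the lipoxygenase Alox12b up by 1.48 ± 0.08. Keratinocyte activation genes rose in 12 of 19 and fell in Sprr2f, Serpinb3b and Hbegf (median 0.58, adjusted p = 0.00161; adjusted p = 0.4 with an estimated correlation), and Krt16 rose by 1.29 ± 0.11. With quantile scaling this list was not called (adjusted p = 0.0678, the highest over 21 settings, with 1.2e-14 the lowest). Cell cycle genes rose in 14 of 20 (median 0.26, adjusted p = 0.001; adjusted p = 0.354 with an estimated correlation). Dct, Pmel, Tyrp1 and Mlana rose among 5 melanocyte genes and Mitf fell (median 1.27, adjusted p = 0.0294; adjusted p = 0.0973 with an estimated correlation). Hair follicle keratins fell in 12 of 15, with Krt72 down by 4.45 ± 0.40, and Tchh, Msx2 and Hoxc13 rose (median -2.10, adjusted p = 0.0239; adjusted p = 0.783 with an estimated correlation).

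Fibroblast and matrix genes fell in 18 of 20 (median -0.29, adjusted p = 6.2e-08; adjusted p = 0.123 with an estimated correlation), with the protease Mmp3 down by 1.68 ± 0.07. Endothelial markers fell in 13 of 14 (median -0.49, adjusted p = 2.5e-06; adjusted p = 0.0973 with an estimated correlation), with Vcam1 down by 1.22 ± 0.07. Cartilage genes rose in 8 of 13 (median 0.35, adjusted p = 0.0387; adjusted p = 0.74 with an estimated correlation), and 2 fell when adjusted over the list alone. The cartilage call was lost without Model replicate 3 (adjusted p = 0.0506), Model replicate 4 (0.0608), IsoL replicate 2 (0.0614) or IsoL replicate 3 (0.165), and held in 9 of 21 settings (0.00728 to 0.165). Skeletal muscle was not called (adjusted p = 0.185), with 7 of 16 up and Myh1 down, but was called higher without IsoL replicate 1 (0.0125) and without the filter on low values (0.00351, with 0.00351 to 0.72 over 21 settings). Adipocyte (0.127), nerve and Schwann cell (0.538), sebaceous gland (0.472), erythrocyte (0.121) and mitochondrially encoded genes (0.66) were not called. In these lists Adipoq, Plin1, Lep and Lipe rose and Fabp4 fell; Mbp, Prx and Ngfr rose and Cdh19 and Scn7a fell; Scd1, Dgat2 and Acsbg1 rose and Scd3 fell; Hba-a1, Hbb-bs and Hbb-bt fell; and mt-Nd6 fell. Of the untested B and plasma cell list, Ighm fell and Igkc was not called.

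**Figure D3:**
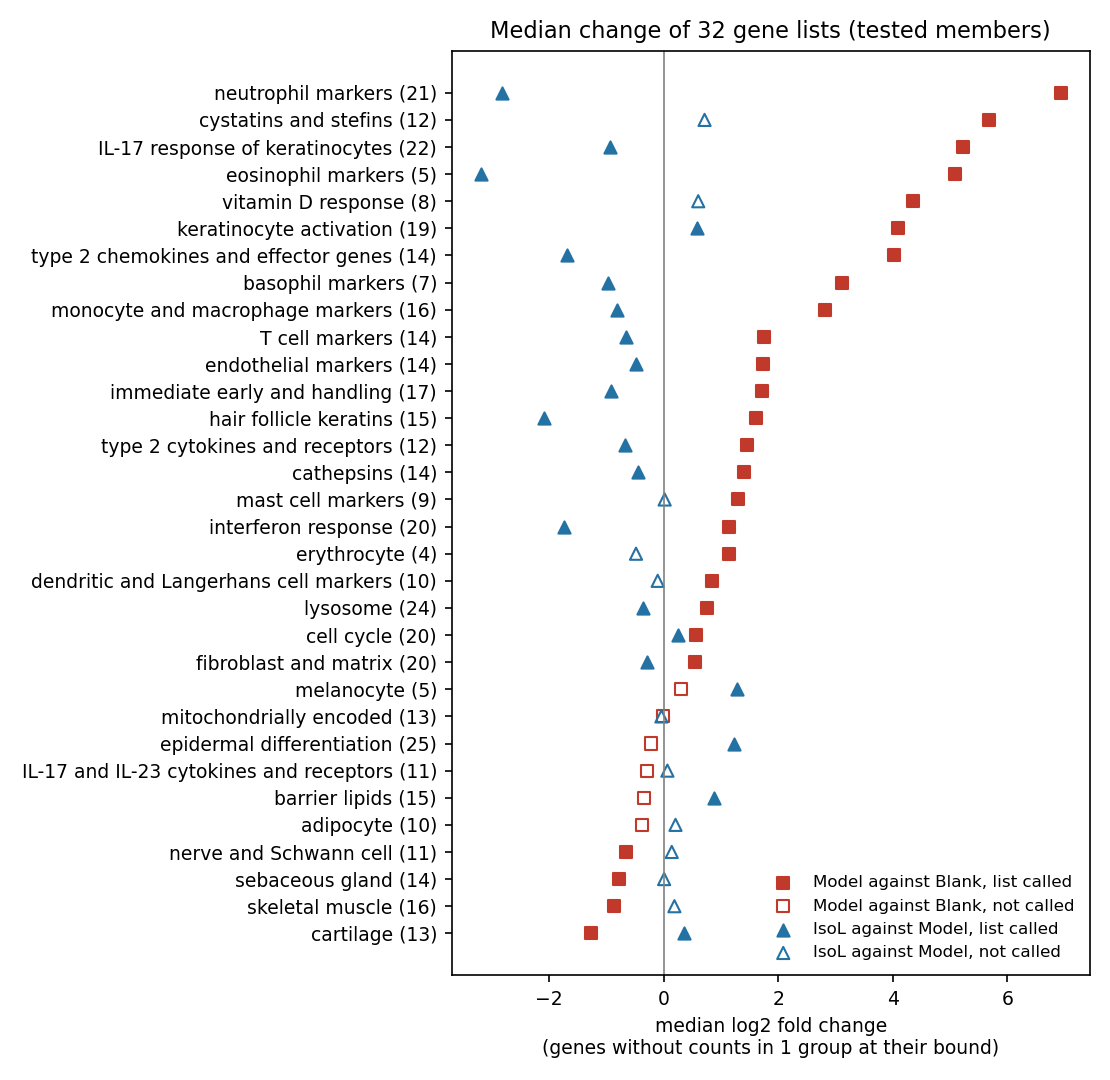
Median log2 fold change of the tested members of 32 gene lists (x axis), with squares for Model against Blank and triangles for IsoL against Model; filled symbols are called lists and the tested members are in brackets. The neutrophil median is 6.93 with genes without counts at their bound in the first comparison and -2.82 in the second, and epidermal differentiation is called in the second alone, at 1.24.

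By the naming rule the largest fall from Model to IsoL was in H2-T22, a gene of the H2 region, the mouse major histocompatibility complex, and its neighbours H2-T23 and H2-T24 fell with it. H2-T22 (ENSMUSG00000056116) had 68.7 ± 3.62 CPM in Blank, 185 ± 4.91 in Model and 4.85 ± 0.487 in IsoL, and from Model to IsoL it fell by 5.25 ± 0.07. H2-T23 fell by 4.57 ± 0.06, to 9.48 ± 0.550 CPM, and H2-T24 fell by 4.31 ± 0.08, to 4.48 ± 0.152 CPM. The 3 genes lie between 36316587 and 36353639 on the minus strand of chromosome 17 (build not given), and in IsoL they were below Blank as well as Model. Of the classical class I genes, H2-D1 did not pass the test (0.06, adjusted p = 0.34) and H2-K1 fell by less, 0.47 (adjusted p = 1.0e-08). H2-Q10, chosen after its values were seen and too low in FPKM for the rule, had 0.994 CPM in Blank, 20.5 in Model and 0.419 in IsoL, a log2 change of -5.59 ± 0.21 from Model to IsoL. H2-T22 shares 51.4% of its 50-base words with other genes, H2-T23 14.8% and H2-T24 2.40%. The other falls named by the rule were in Retnlg, Ly6g, Krt72, Ccl24 and Ccr3, and the largest rises by it were in Rps2-ps6 (5.78 ± 0.33), Ndufs5-ps, Rps2 (3.59 ± 0.08), Ecel1, Gsta1, Scgb1b27, Krt4 and Tslp. Of these, Rps2-ps6 shares 92.1% of its words with other genes, Gsta1 90.7%, Ndufs5-ps 70.3% and Rps2 43.6%, so their counts are uncertain. No called rise of 4-fold or more from Blank to IsoL was found for Rps2-ps6, Ndufs5-ps or Rps2. Ndufs5-ps was also among the largest falls from Blank to Model.

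**Figure D4:**
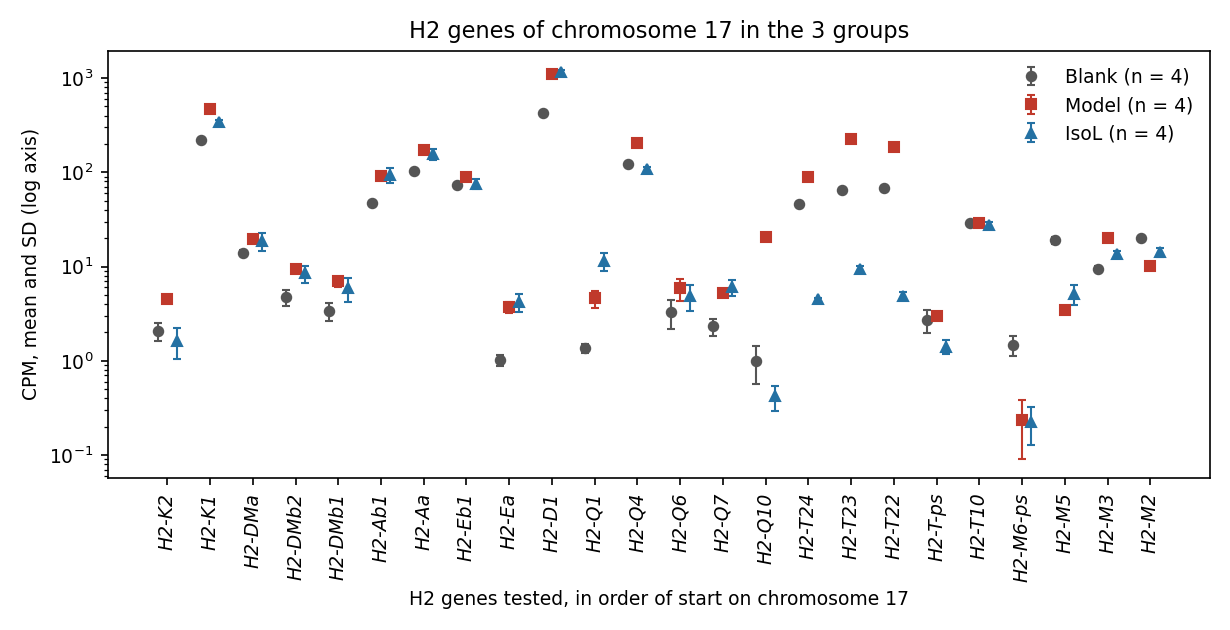
CPM (y axis, log scale, mean and SD of 4 libraries) of the tested H2 genes in order of their start on chromosome 17 in the 3 groups. H2-T24, H2-T23 and H2-T22 have means of 4.48, 9.48 and 4.85 CPM in IsoL, below both other groups.

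By edgeR, 7587 of 15403 genes changed between Model and IsoL, 3716 up and 3871 down, and 361 rose and 887 fell at least 2-fold. Libraries did not overlap for 6578 genes (chance 2.86%). Of 32 lists, 21 were called, 6 up and 15 down. With an estimated correlation 9 calls held: the IL-17 response, neutrophils, both type 2 lists, eosinophils, monocytes and macrophages, the interferon response, epidermal differentiation, and immediate early genes. Their adjusted p with it was higher, from 0.000131 (interferon response) to 0.0425 (type 2 cytokines and receptors, and monocytes and macrophages). It was 0.0118 for epidermal differentiation and 0.0322 for the IL-17 response. Adjusted over the list alone, the counts were the same for 29 lists. The share of called genes that rose was 49.0% with TMM, 39.3% without scaling factors, 33.4% with TPM and 58.5% with quantile scaling. With the stricter filter the type 2 cytokine list (adjusted p = 0.0512, over all settings 0.00135 to 0.0512), the basophil list (0.285, 0.000176 to 0.285) and the hair follicle list (0.804, 3.2e-16 to 0.804) were not called, and with quantile scaling neither was the melanocyte list (0.082, 3.5e-05 to 0.082).

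The next question is where IsoL lies between Model and Blank for the genes that changed with MC903. Whether the IsoL ears received MC903 is not given in the labels. Of 8 vitamin D response genes, 7 were higher in IsoL than in Blank and 0 lower. Camera gave an adjusted p of 7.7e-05, or 0.00358 with an estimated correlation. Cyp24a1 had 4633 to 5650 CPM in the IsoL libraries and 1.08 to 1.77 in Blank. These values argue against ears without MC903, but the dose and schedule are not given. What follows therefore compares levels and does not show that a change was reversed. Of the 5436 genes higher in Model than in Blank, 2740 (50.4%) were lower in IsoL than in Model, 1094 were higher and 1602 did not pass the test. Of the 2149 that were at least 2-fold higher in Model, 1578 (73.4%) were lower in IsoL than in Model and 274 higher. Of the 5369 genes lower in Model than in Blank, 1709 (31.8%) were higher in IsoL than in Model and 490 lower. The median distance of IsoL from Model towards Blank, as a share of the log2 change between Blank and Model, was 27.6% for the genes higher in Model and 15.8% for those lower, and 35.9% and 17.6% for the genes at least 2-fold apart. Among the genes higher in Model, 4301 differed from Blank in the same direction in IsoL, 921 showed no called difference and 214 lay past Blank. Ctsb, Cxcl2, S100a8 and Csf3r belong to the first of these. Both comparisons use the same Model libraries, which alone gives opposite signs. The total of 4449 genes on the Blank side of Model in IsoL is called moved back in what follows. In simulated unchanged groups its mean was 0.1, but hardly any gene is called there, so a value near 0 was set in advance. The counts of 2740 and 1709 for the 2 directions compare with 1366 and 1295 if the calls were independent. With the Model libraries split 2 and 2 between the comparisons, the mean was 3385 (3289 to 3500). Each of these fits holds fewer Model libraries, so the lower total cannot be credited to the sharing alone. The split means of 2294 and 1091.5 for the 2 directions compare with 1004 and 827 if the calls were independent. Across genes, which are not independent replicates, the covariance of the log2 changes was -0.48, with a jackknife SE of 0.0297 over the 12 libraries. The simulated value was -0.02, a difference of -0.46. The SE does not cover the processing: the covariance was -0.95 without the filter on low values, -0.25 with quantile scaling and -0.24 with limma-trend and with library weights. The correlation was -0.54 both observed and simulated, so with shared Model libraries it cannot tell the 2 apart. With the Model libraries split 2 and 2, where none is shared, it was -0.49 (-0.512 to -0.474).

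IsoL against Blank asks what sets isoliensinine ears apart from untreated ones. The vitamin D response argues against IsoL ears without MC903, so differences from Blank cannot be credited to isoliensinine alone. IsoL ears had higher levels of activated keratinocyte, vitamin D response and IL-17 response genes. Ctsb was 2.76-fold higher than in Blank (1059 ± 48.5 against 384 ± 4.87 CPM, n = 4 each, adjusted p = 3.1e-17). Cyp24a1 reached 5323 ± 466 CPM against 1.53 ± 0.308 in Blank, a rise by 11.76 ± 0.12, and Tslp was 163-fold higher.

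Neutrophil markers were higher in 19 of 21 and Mpo fell by 2.45 ± 0.20 (median 4.82, or 4.80 with 2 genes at their bound; adjusted p = 1.8e-08). Ly6g had 13 counts in IsoL, at least 4.52-fold higher than in Blank, a call lost with quantile scaling and with library weights. Fpr1 rose by 6.25 ± 0.40, S100a8 by 3.05 ± 0.16, S100a9 by 3.07 ± 0.19, Csf3r by 5.72 ± 0.12, and in the IL-17 response list, where 21 of 22 genes rose (median 3.44, adjusted p = 1.2e-10), Cxcl5 by 8.13 ± 0.13, Cxcl2 by 5.81 ± 0.20 and Cxcl1 by 4.03 ± 0.11. Il17ra rose by 0.79 ± 0.05. The IL-17 and IL-23 list was not called (adjusted p = 0.414, 6 up of 11). Its member Il23a rose by 2.08 ± 0.55, which reversed to -0.06 with quantile scaling. Il17a, with 2 counts in IsoL and 0 in Blank, is given no fold (exact permutation p = 1). Il13 had a ratio of 2.16 (1.08 to 4.57), which did not pass (exact permutation p = 0.0571, adjusted 0.0686), and neither did Il4 (0.17 ± 0.23, adjusted p = 0.518), whose sign turned without IsoL replicate 1 (-0.01) and under 4 other settings.

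Type 2 cytokines and receptors rose in 8 of 12 and Gata3 fell (median 1.08, adjusted p = 0.00431). Type 2 chemokines and effector genes rose in 9 of 14 and Ccr4, Retnla and Postn fell (1.15, adjusted p = 0.0385; adjusted p = 0.209 with an estimated correlation). Eosinophil markers were not called (adjusted p = 0.186), although Ear2, Siglecf, Ccr3 and Alox15 rose, and were called higher with TPM values (0.0375, with 0.0375 to 0.559 over 20 settings); Siglecf (1.89) and Ccr3 (1.68) reversed to -0.00 and -0.03 with quantile scaling. Basophil markers rose in 6 of 7 (1.67, adjusted p = 0.00378; adjusted p = 0.135 with an estimated correlation), mast cell markers in 8 of 9 with Mrgprb2 lower (1.46, adjusted p = 0.00026), and all 16 monocyte and macrophage markers rose (2.13, adjusted p = 4.3e-11). Dendritic and Langerhans cell markers rose in 7 of 10 and Cd207 fell (0.75, adjusted p = 0.0282; adjusted p = 0.402 with an estimated correlation). T cell markers were not called (adjusted p = 0.0664, 10 up, Cd3g and Trdc down) but were without IsoL replicate 2 (0.0399) and in 8 of 20 settings in all (0.00068 to 0.129). Of 20 interferon response genes, 14 fell and Oasl1, Cxcl9, Cxcl10, Gbp2, Igtp and Iigp1 rose (median -0.57, adjusted p = 0.00735; adjusted p = 0.206 with an estimated correlation, and 0.0978 with TPM values, where all settings gave 0.000355 to 0.0978). Mx2 fell by 2.35 ± 0.08 and Cxcl9 rose by 4.86 ± 0.13. Both tested members of the B and plasma cell list, Ighm and Igkc, rose.

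Cathepsins rose in 10 of 14 and Ctsf and Ctso fell (median 1.33, adjusted p = 0.000613), with Ctsl up by 2.36 ± 0.06. Cystatins and stefins rose in 10 of 12 and Cst3 fell (5.93, adjusted p = 1.3e-06). Lysosome genes rose in 18 of 24 (0.51, adjusted p = 0.000277; adjusted p = 0.207 with an estimated correlation). Vitamin D response genes rose in 7 of 8 (3.01, adjusted p = 7.7e-05). Immediate early and handling genes rose in 11 of 17 and Fosb, Egr2 and Hspa1a fell (0.73, adjusted p = 0.00518; adjusted p = 0.137 with an estimated correlation). Keratinocyte activation genes rose in 17 of 19 and Serpinb3b and Ereg fell (4.67, adjusted p = 1.4e-08), with Krt16 up by 6.69 ± 0.14. Epidermal differentiation genes rose in 17 of 25 and Flg2, Ivl, Krt2, Dsg1a and Lce1m fell (1.11, adjusted p = 0.000764; adjusted p = 0.135 with an estimated correlation), with Flg up by 3.44 ± 0.12. Barrier lipid genes rose in 11 of 15 and Slc27a4 and Fa2h fell (0.80, adjusted p = 0.00238; adjusted p = 0.327 with an estimated correlation). All 20 cell cycle genes rose (0.87, adjusted p = 1.7e-06; adjusted p = 0.163 with an estimated correlation), as did all 5 melanocyte genes (1.58, adjusted p = 0.0158; adjusted p = 0.207 with an estimated correlation).

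Endothelial markers rose in 12 of 14 and Prox1 fell (1.15, adjusted p = 2.6e-05; adjusted p = 0.0728 with an estimated correlation). All 16 skeletal muscle genes (median -0.71, adjusted p = 3.5e-05; adjusted p = 0.407 with an estimated correlation) and all 13 cartilage genes fell (-1.01, adjusted p = 4.2e-06; adjusted p = 0.217 with an estimated correlation). Nerve and Schwann cell genes fell in 9 of 11, or 10 adjusted over the list alone (-0.60, adjusted p = 0.000613; adjusted p = 0.101 with an estimated correlation), and sebaceous gland genes in 9 of 14 (-0.60, adjusted p = 0.00299; adjusted p = 0.209 with an estimated correlation). Not called were fibroblast and matrix (adjusted p = 0.11, with Col1a2, Col6a1, Fap and Sparc lower and 9 of 20 higher, but called higher with DESeq2, 0.000307, and without the filter on low values, 1.6e-06, with 0.889 the highest of 21 settings), hair follicle keratins (0.464, but 0.0178 without IsoL replicate 2, the lowest of 21 settings, with 0.958 the highest), adipocyte (0.445), erythrocyte (0.104) and mitochondrially encoded genes (0.414). In those, Tchh and Hoxc13 rose and 7 of 15 hair follicle genes fell, Lipe rose and Adipoq, Plin1 and Cfd fell, Hba-a1, Hbb-bs and Hbb-bt rose (4 genes adjusted over the list alone), and mt-Nd5 and mt-Atp6 fell. The change of mt-Atp6 (-0.30) was not called without Blank replicate 4 (-0.23) or IsoL replicate 1 (-0.23), and mt-Nd1, up by 0.28, reversed to -0.05 with TPM values.

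By the naming rule the largest rises over Blank were in Cyp24a1, Akr1d1 (9.82 ± 0.22), Rptn (8.89 ± 0.11), Tmprss11b, Ecel1, Krt36, Lce3d and Saa3. The largest falls were in H2-T22 (-3.82 ± 0.07), Mrgprb3, Mir8116, Il1f10, H2-T24 (-3.36 ± 0.08), Apol7a, Col4a6 and Serpina3b. By edgeR 10853 of 15403 genes changed, 5617 up and 5236 down, with 1781 rises and 941 falls of at least 2-fold, and libraries did not overlap for 9813 genes (chance 2.86%). Of 32 lists 24 were called, 19 up and 5 down, and 9 held with an estimated correlation, those listed for this comparison without a second p. For these 9 the adjusted p with it ran from 0.00358 (vitamin D response) to 0.0356 (mast cells). Adjusted over the list alone, the counts were the same for 30 lists. The share of called genes that rose was 51.8% with TMM, 35.9% without scaling factors, 42.0% with quantile and 27.4% with TPM values, with the median change of all genes at 0.02, -0.18, -0.08 and -0.29. Across the 3 comparisons, 22 of 190 named genes share 20% or more of their 50-base words with other genes, Krt6a, Krt6b, Krt16, Chil3 and Ctsl among them, and their levels are uncertain to that extent.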

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

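Chosen only after the result was seen were the tests of the chromosome 17 window, of the non-immune lists, of the vitamin D list and of library depth. Of 69 groups of 4 libraries examined, 3 held a library far from the others, where chance alone gives about 3.45. Il17a stood at 0.126 CPM in IsoL replicate 3 and at 0 in the other 3 IsoL libraries. H2-T22 stood at 74.1 CPM in Blank replicate 3 against 66.7 to 67.4 in the others, and H2-T24 at 49.0 CPM in Blank replicate 2 against 44.4 to 45.2.

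In IsoL 38 genes lay at least 4-fold away from both other groups, 17 lower and 21 higher, H2-T22, H2-T23 and H2-T24 among them. A fall of the whole class I presentation machinery below Blank is argued against by the 15 other genes of that machinery. Their median log2 change from Blank to IsoL was 0.36, with a bootstrap SE of 0.124 (12 called higher, 2 lower). A fall from Model is not judged by this median. By camera with the preset correlation, the wider antigen processing and presentation pathway rose from Blank to Model (adjusted p = 4.1e-06). Of its 73 genes, 53 rose and 12 fell. From Model to IsoL the pathway was lower by the same test, with 12 up and 35 down (adjusted p = 0.000388). A broader fall from Model thus stays open. A strain or sequence difference linked to the H2 region of chromosome 17 cannot be told apart from a regulated change, since the window was drawn around these 3 genes after they were seen; besides them, 3 of the 38 genes lie in it, ENSMUSG00000120973, Gm23864 and Gm8810, also chosen after their values were seen. Random draws of as many tested genes as remained gave a median of 0 and a 95th percentile of 1, so the count goes with a linked region, but it is no support for an explanation found from the same region. Reads shared with near-identical copies cannot be told apart from a change of the gene itself, as the median percent of shared 50-base words was 1.55 for the 36 genes with a sequence, between the median (0.619) and the 95th percentile (2.74) of random draws. The strain is not given, the reads were not used here, and a regulated change of these genes in isoliensinine ears also stays open, untested.

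The neutrophil, eosinophil, and monocyte and macrophage lists were lower and the epidermal differentiation list higher in IsoL than in Model, also with an estimated correlation. The interferon response list and the immediate early and handling list, which also responds to tissue handling, were lower in the same way. The mast cell and the dendritic and Langerhans cell lists were not called, and the calls of T cells and basophils (lower) and of keratinocyte activation and barrier lipids (higher) were lost with an estimated correlation. A lower share of immune cell RNA that raises all other cell types alike was examined in 7 non-immune lists. Their medians spanned 1.72 on the log2 scale (95% bootstrap range over genes 1.60 to 2.04). The highest, epidermal differentiation, itself defines the pattern. Besides it, endothelial markers (-0.49, -0.75 to -0.41) and fibroblast and matrix genes (-0.29, -0.59 to -0.25) were lower. The other medians ran from 0.19 (skeletal muscle) to 0.58 (keratinocyte activation). A rise of all these types alike is argued against, but changes within the cell types were not separated. Scaling is argued against as well, since over 5 scalings the epidermal differentiation median was never under 1.06 and the neutrophil median stayed between -2.90 and -2.34. A stronger vitamin D receptor response in IsoL cannot be told apart from other explanations: the vitamin D list was not called (adjusted p = 0.538), with members going both ways and Cyp24a1 up. An effect of isoliensinine, and a difference in MC903 exposure, sampling day or tissue handling that the labels do not give, may each account for the pattern and were not tested.

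The spread between the IsoL libraries, 9.20%, was wider than in Blank (3.57%) or Model (4.70%). Depth is argued against, as the IsoL libraries had the highest mean total, 17895137 counts against 16316960 in Blank and 15402874 in Model. A single deviating library is argued against, as the lowest value after leaving out 1 IsoL library was 8.84%, above 1.5 times the Model value (7.05%). Differences in the tissue types of 8 lists cannot be judged as a cause. Without the genes of these lists and those correlated with them, the spread was 9.62% in IsoL and 4.26% in Model over 5297 genes. Leaving out genes by their correlation with random values instead gave IsoL spreads both below and above this 9.62%. The removal thus does not set these tissue types apart from random values, and no conclusion is drawn from it. Differences in immune cell content or in the response of single ears were not covered by this test and may contribute.

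Other splits of the libraries were examined for each count. For the genes changed, 1 of 35 splits, the real one, gave as many in each comparison. The counts were 10805, 7587 and 10853 in the real split, and 0 at most in the others. A share of 1 of 35 is the smallest these splits allow, and it argues against a chance assignment of libraries to groups. Mixed groups have a wider spread, so the size of the gap carries no further weight. For the lists called in Model against Blank, 1 of 35 splits, the real one, gave as many, with 26 lists and 25 at most in the others. The count thus hardly sets the real split apart, and chance is not clearly excluded for it. For IsoL against Model, 2 of 35 splits gave as many lists, 21 in the real split and 21 at most in the others, and for IsoL against Blank 2 of 35, with 24 against 25, so chance is not excluded for these list counts. For the genes moved back, 1 of 100 splits of the 12 libraries gave as many, 4449 against 1516 at most. A chance assignment of libraries to groups is argued against. Such splits mix the groups, so they do not test movement towards Blank.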

How the results depend on the processing

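DESeq2 and the fit without scaling factors were chosen after seeing the data; limma-trend on log2(FPKM + 1) had been named as the main test and became an alternative only after the counts were seen. The other alternatives were planned. The pseudocount, quantile, TPM and library weight settings were run with limma-trend, so they change the test as well as the choice they name. Of 339 named gene results, 327 had the same direction and call under all settings. Requiring a log2 change of 1 or more gave 3253 genes for Model against Blank, 1248 for IsoL against Model and 2722 for IsoL against Blank, fewer by construction. With the stricter filter, which tests fewer genes, the counts were 6219, 4864 and 6322, and 2802 genes moved back. With an estimated correlation 16, 9 and 9 lists were called. This test runs on the counts and not on the gene statistics. It changes the statistic as well as the correlation, and the cause was not tested. Fry, which does not compare the members with other genes, called 29, 26 and 29 lists, more than the main test in each comparison. The covariance stayed negative: -0.43 with a pseudocount of 0.1, -0.95 without a filter, -0.37 with the stricter filter, -0.25 with quantile scaling, -0.34 with TPM, -0.24 with library weights and -0.24 with limma-trend; the cause was not tested. Leaving out 1 library gave 10362 to 10411, 6899 to 7543 and 10426 to 10742 genes, 4041 to 4435 moved back, a covariance of -0.498 to -0.463, and 26, 20 to 22 and 24 to 26 lists.

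Among the named genes the sign changed in 11 cases, each 1 result under 1 setting, and the cause was not tested. With TPM these were mt-Nd1 in Model against Blank (-0.0402) and in IsoL against Blank (-0.0501) and Il4 in IsoL against Blank (-0.125). With quantile scaling they were Mpo in IsoL against Model (0.00521) and, in IsoL against Blank, Il23a (-0.0566), Siglecf (-0.00279) and Ccr3 (-0.0294). Il4 in IsoL against Blank, not called, also turned with a pseudocount of 0.1 (-0.00823), with limma-trend (-0.0105), without scaling factors (-0.0248) and, among the fits that leave out 1 library (-0.0144 to 0.420), without IsoL replicate 1. In another 40 such cases the call was lost without a change of sign. These fell on Dct and mt-Nd2 (Model against Blank), Actn3 (IsoL against Model), Ly6g, Il23a, Siglecf and mt-Atp6 (IsoL against Blank) and mt-Nd1. Actn3, up by 0.59, was not called without Model replicate 1 (0.55), Model replicate 2 (0.57) or IsoL replicate 2 (0.24). Of the lists not yet named as unstable, the highest adjusted p over the settings exceeded 0.05 in Model against Blank for dendritic cells (3.0e-05 to 0.0979), cell cycle (6.6e-05 to 0.0674), hair follicle keratins (1.0e-08 to 0.576) and erythrocytes (0.0164 to 0.181), and in IsoL against Blank for type 2 chemokines (4.0e-08 to 0.0894), basophils (2.0e-05 to 0.0542), dendritic cells (6.3e-05 to 0.147) and melanocytes (0.000713 to 0.0616).

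Replicate numbers did not pair the libraries: residuals of libraries with the same number had correlations of -0.132 to 0.0324. With the replicate number as a block, 10737, 7482 and 10800 genes changed and 4409 moved back. Of simulated 1.2-fold changes, 24% were recovered in Model against Blank, 38% in IsoL against Model and 26% in IsoL against Blank; the cause was not tested.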

Other observations

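The KEGG pathways, taken from the deposited annotation, were tested only after the lists had been seen. Of 335 pathways, camera with the preset correlation of 0.01 called 104 in Model against Blank, 97 in IsoL against Model and 67 in IsoL against Blank. The pathways were not tested with an estimated correlation, with which many calls of the gene lists were lost. Proteasome genes, which degrade proteins, were higher than in Blank in both other groups: of 54, 42 rose and 1 fell in Model (adjusted p = 2.1e-05), and 47 rose and 0 fell in IsoL (3.9e-07). Ribosome biogenesis genes, which make ribosomes in growing cells, were higher in IsoL than in Model, with 43 of 81 up and 5 down (median 0.20, adjusted p = 0.000381). Aminoacyl-tRNA biosynthesis genes moved the same way, with 20 of 45 up and 1 down (adjusted p = 0.000438), as did steroid biosynthesis, with 14 of 18 up and 3 down (0.000599), and cytochrome P450 metabolism of xenobiotics, with 21 of 49 up and 5 down (0.00452). Complement and coagulation genes were lower in IsoL than in Model, with 35 of 48 down and 1 up (adjusted p = 6.4e-10).

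By the same test with the preset correlation, genes of branched-chain amino acid and fatty acid metabolism were lower in MC903 ears. Of 47 genes of valine, leucine and isoleucine degradation, 33 fell and 6 rose in Model against Blank (median -0.46, adjusted p = 0.00016), and of 60 fatty acid metabolism genes 37 fell and 9 rose (0.000803). Both were also lower in IsoL against Blank, with 32 of 47 down (adjusted p = 0.00107) and 34 of 60 down (0.00497). Circadian rhythm genes were also lower, with 17 of 28 down in Model against Blank (adjusted p = 0.00847) and 18 of 28 down in IsoL against Blank (0.00789); the hour of sampling is not given in the sources used here.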
